A study of Mus musculus with 12 samples.

How the data were processed

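Microglia, the resident macrophages of the brain, had been isolated from the hippocampus of male BALB/c mice at postnatal day 28 with a Percoll gradient followed by fluorescence-activated sorting, per the labels' protocols. The 2 groups were control pups and pups exposed to brief daily separation (BDS), in which the litter was taken from its mother for 15 min a day from postnatal day 1 to 21. Each group held 6 samples, all from different litters per the submitters' design text, so the replicates are biological. RNA (2 ng) was converted to cDNA, amplified in 5 rounds of PCR and hybridized to a NanoString nCounter mouse immune panel, in which a fluorescent barcode is counted for each transcript without sequencing. No replicate number was shared between the groups, so no pairing of samples was used.

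The deposited raw table holds whole-number barcode counts per probe, with no normalization by the authors. It lists 573 probes, of which 545 are endogenous genes, 14 are housekeeping genes, 8 are negative controls and 6 are positive controls. The second table holds normalized counts that the authors had scaled to positive controls and housekeeping genes and rounded to whole numbers, so these deposited values are treated as scores and not as counts. Per the file headers, that table also gives the authors' group means as scores, the percent of samples above background, the fold (a linear ratio, BDS over control) and an unadjusted p-value for each gene. The software that read the barcodes is not given in the sources used here. The design text speaks of 5 housekeeping genes and names 6. In each sample the deposited normalized values equal the counts times 1 factor, and those factors match the geometric mean of Alas1, Gapdh, Oaz1, Polr1b and Tbp (spread of the product over samples 0.00084%, against 1.65% with Sdha added). On counts scaled by those 5 genes, an equal-variance test gave the deposited p-value within 0.001 for 536 of 545 genes.

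Counts were divided by the geometric mean of the 6 named housekeeping genes of the same sample, set relative to the mean over samples. This scaling sets the level against which every gene is called higher or lower. A gene was kept where at least 40% of the samples (5 of 12) lay above the mean plus 2 SD of the negative controls of the sample, which kept 357 genes. The 2 groups were compared with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3, housekeeping size factors, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are BDS over control, and values are normalized counts given as mean ± SD over 6 samples per group. Gene lists were compared with the other genes of the panel by camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation, and tested by themselves with fry. A list needed at least 3 present genes. Single measures of library quality were compared with two-sided exact permutation tests over 924 rearrangements, whose smallest possible p is 0.00216.

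The test, the lists, the markers of other cell types, the naming rule and most alternatives were fixed before the data were examined. By that rule the text names genes past the threshold, filled up to 24 with the genes of smallest unadjusted p, up to 3 present members per list with the smallest p, the 10 genes with the highest mean count and the housekeeping genes. List members with an unadjusted p of 0.25 or above were left unnamed. That limit was set after their values and their alternatives had been seen; it left out 8 genes, whose sign changed in 32 of 245 combinations of gene and alternative, none past the threshold. Some genes that the rule names are not reported here. Gene names are those of the files. Of the 545 RefSeq accessions, 535 were found in the GRCm38.p6 gene table, where 13 carry another symbol. No genome build is named in the files, so no coordinates are given.

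Alternatives covered other scalings, the housekeeping genes without the most variable one, DESeq2 1.42.0, limma on log2 values with pseudocounts of 1 and 10, the deposited scores, voom with quality weights, robust edgeR, other filters and background treatments, a threshold of 0.1, 1 surrogate variable (sva 3.50.0) and each sample left out in turn. Alternatives added after seeing the data were the authors' 5 housekeeping genes, the genes the authors list as present, the removal of 3 BDS samples with low housekeeping counts, covariates for the housekeeping count and the Rpl19 to Polr2a ratio, background subtraction, fry with TMM scaling, the 2 other filters with an estimated correlation and adjustment of the deposited p-values.

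The test was checked on counts simulated for the 357 genes of the BDS and control comparison, with 40 or 200 genes changed and 10 runs each. With 40 changed genes, 14 of 100 changes of 1.25-fold, 57 of 100 of 1.5-fold, 92 of 100 of 2-fold and 98 of 100 of 3-fold passed the threshold. With 200 changed genes these shares were 34.2%, 74.4%, 93.4% and 99.8%, and with none changed no gene was called. Of the unchanged genes, 16 of 3170 were called with 40 changed and 33 of 1570 with 200 changed. Each gene was simulated independently, without variation shared between genes of a sample. These shares may therefore not hold for the real samples. Total counts ranged from 641756 to 1409376 per sample. The median half-width of the 95% interval of a log2 fold change was 0.32. Pearson correlations of samples, taken across genes, ran from 0.973 to 0.995 within groups. The postnatal day 14 companion data were not analysed here.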

Results

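Transcripts of 545 immune genes were counted in hippocampal microglia of 28-day-old male mice, 6 controls and 6 that had undergone brief daily separation (BDS) from the mother. Total counts were 893936 to 1409376 in the control samples and 641756 to 1171355 in the BDS samples. The means differed 1.30-fold (exact permutation p = 0.063, two-sided; adjusted p = 0.11 over 9 quality measures). Of the panel, 357 genes lay above the negative-control probes in enough samples to be tested. Per sample, 361 ± 18 genes were above background in controls and 324 ± 20 in BDS (SD, n = 6; exact permutation p = 0.0087, two-sided; adjusted p = 0.078). Among the 10 genes with the highest mean counts, Csf1r, the receptor on which microglia depend for survival, had 84924 ± 3867 normalized counts in controls and 97734 ± 21438 in BDS. Its log2 fold change of 0.20 turned to -0.095 without BDS 21, BDS 25 and BDS 55. Ctss, a lysosomal protease, had 87173 ± 7990 and 91602 ± 13063, and Itgam, an integrin chain of the complement receptor, had 39933 ± 2905 and 36367 ± 5675 (SD, n = 6). C1qa and C1qb, which encode chains of the complement component C1q, were also among the 10 most abundant, as were Cd81, Cd164, Tgfbr1, Tgfbr2 and Ccr6. The log2 fold changes of Ctss, Cd81 and C1qb also turned without those 3 samples, from 0.07, 0.01 and 0.16 to -0.11, -0.12 and -0.16. None of these 10 passed the adjusted threshold.

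The main comparison asked which immune genes of microglia differ at this age after early separation. The genes with the smallest p-values were mostly lower in BDS. Il21r, a cytokine receptor chain, had 2214 ± 190 normalized counts in controls and 1660 ± 239 in BDS (SD, n = 6). All 6 BDS samples lay below the lowest control, at a log2 fold change of -0.41 ± 0.10 (SE; edgeR quasi-likelihood test, adjusted p = 0.17). Il6st, the shared signalling chain of the interleukin-6 family of receptors, was at 6702 ± 624 and 5139 ± 765, and Il4ra, the interleukin-4 receptor chain, at 1071 ± 173 and 798 ± 106. Tlr9, an endosomal sensor of unmethylated DNA, was at 5293 ± 226 and 3971 ± 772. Ski and Tgfbr2, a repressor and a receptor of the TGF-beta pathway, differed by -0.30 ± 0.08 and -0.31 ± 0.09 on the log2 scale (SE), and for both genes, as for Cd82, all 6 BDS samples lay below every control. Tlr3, Tlr5, Notch1, Cmklr1, Gpr183, Ccr6, Cd164, Zeb1, Itgb1, Il17ra, Ptprc and Icosl were lower by 0.20 to 0.39 on the log2 scale. Cybb and Lck were lower near the detection limit, Cybb at 25.0 ± 9.1 normalized counts in controls and 12.5 ± 5.4 in BDS. Only Ebi3, Il6 and Tnfrsf13b were higher at an unadjusted p under 0.05, Ebi3 at 88.2 ± 9.7 and 116 ± 20 normalized counts and Il6 at a log2 fold change of 0.59 ± 0.22 (SE). Before scaling, mean counts of Ebi3 were 101 in controls and 103 in BDS. Without BDS 21, BDS 25 and BDS 55, the BDS samples with the lowest housekeeping counts, the log2 fold change of Ebi3 went from 0.39 to 0.20, that of Tnfrsf13b from 0.59 to 0.18 and that of Il6 from 0.59 to 0.40. With background subtracted, the log2 fold change of Il6 was 0.86, with an unadjusted p of 0.16 in limma.

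**Figure D1:**
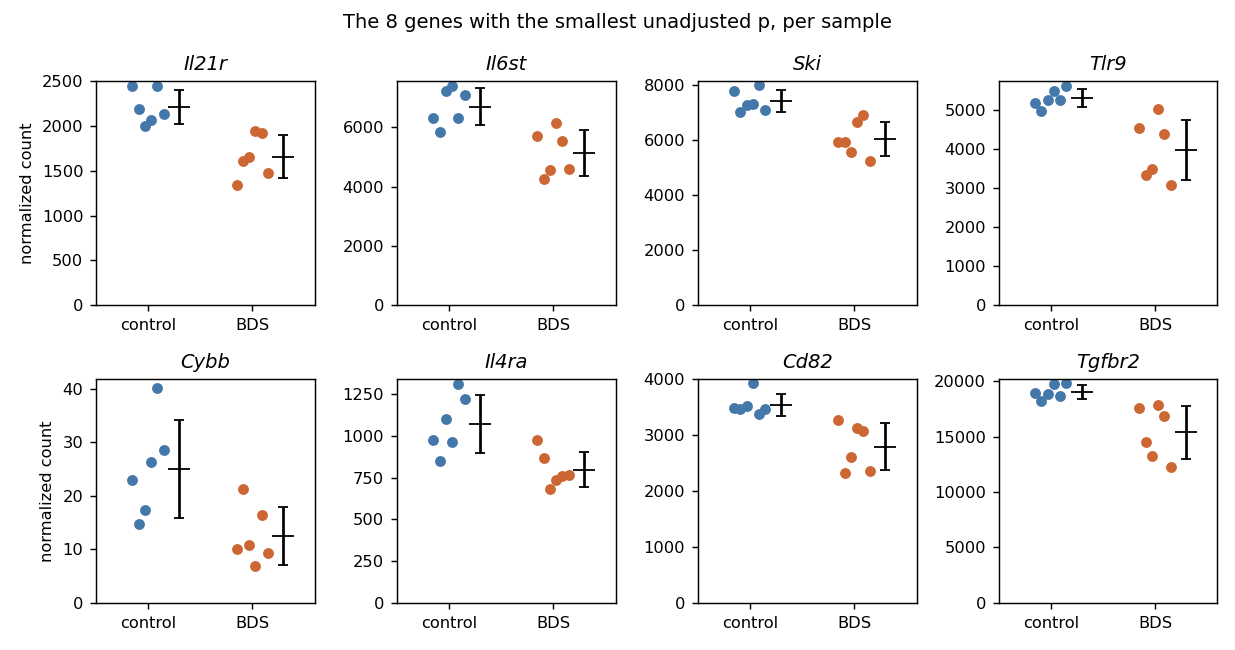
Normalized counts (y axis, from 0) of the 8 genes with the smallest unadjusted p in each of 6 control and 6 BDS samples. Points are samples, and the bars beside them give the mean ± SD. For Il21r, Ski, Cd82 and Tgfbr2 all 6 BDS samples lie below the lowest control, while no gene passes the adjusted threshold.

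No gene passed the adjusted threshold in the edgeR test of 357 genes, where the smallest adjusted p was 0.17. At an unadjusted p under 0.05 there were 44 genes, 41 lower and 3 higher in BDS, against an average of 17.9 in all expected by chance. Of 100 splits of the 12 samples, the real one included, 14 gave at least 44 such genes, so chance cannot be excluded. The counts of lower and higher genes depended on single samples. Without BDS 7 they were 87 and 8, with 4 genes past the adjusted threshold, and without BDS 55 they were 22 and 4. DESeq2 with the same scaling called 6 genes, Il21r, Il6st, Ski, Tlr9, Il4ra and Cd82, and voom with quality weights called 16, while DESeq2 with its own size factors called 0. The balance of lower and higher genes depended on the scaling. TMM scales each sample to the tested genes themselves, which places the panel median near 0 by construction. The median log2 fold change of all 357 genes was -0.10 with the housekeeping genes and -0.01 with TMM, which gave 14 lower and 18 higher genes in place of 41 and 3. The 24 genes of smallest p kept their sign with TMM, 16 of them at an unadjusted p under 0.05, among them Il21r at -0.31 and Il4ra at -0.33 on the log2 scale. These 24 were picked for small p in the same samples, so their sign under another scaling is no independent support. Of all 44 genes, 17 were also at an unadjusted p under 0.05 with TMM. BDS 21, BDS 25 and BDS 55 had the lowest housekeeping counts, with scaling factors of 0.61, 0.65 and 0.85. Their Rpl19 to Polr2a count ratios were 0.79, 0.61 and 0.47, against 0.11 to 0.27 in the other 9 samples. Of the 14 housekeeping genes, Rpl19 was the most raised in BDS (log2 ratio 0.45) and Polr2a the most lowered (-0.52). A ratio of these extremes differs between the groups by construction, so it is no independent measure of RNA quality. Without these 3 samples 20 genes were lower and 0 higher at an unadjusted p under 0.05, and 0 passed the adjusted threshold. Of these 20 genes, 10 were among the 44, and 10 of the 24 genes of smallest p stayed at an unadjusted p under 0.05.

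**Figure D2:**
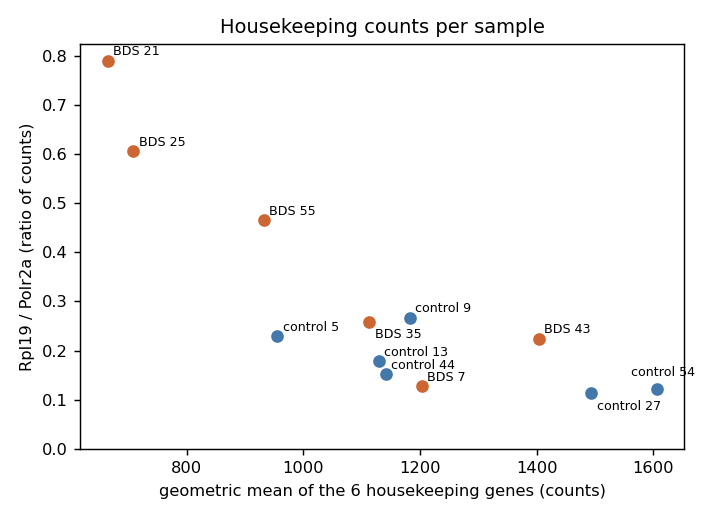
Ratio of Rpl19 to Polr2a counts (y axis) against the geometric mean of the counts of 6 housekeeping genes (x axis) in each of the 12 samples. Points are samples, coloured and named by group. BDS 21, BDS 25 and BDS 55 have ratios of 0.79, 0.61 and 0.47, above the other 9 samples.

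The authors' deposited table lists 364 genes as present. Of these, 39 have a deposited p under 0.05, 33 lower and 6 higher in BDS, and 34 of the 39 were also at an unadjusted p under 0.05 in edgeR. For Il21r the authors' deposited table gives group means of 2353 and 1788, a fold of 0.76 and a p of 0.0022. Adjusted over the present genes, the smallest of these deposited p-values became 0.25.

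The fixed gene lists asked whether pathways or cell types shifted together relative to the other genes of the panel, of which 236 of 357 had log2 fold changes below 0. TGF-beta signalling had the smallest p among the pathway lists. Of its 9 present genes, 8 had log2 fold changes below 0 and 7 lay below the panel median, with a list mean of -0.19 (Ski, Tgfbr2 and Smad3 had unadjusted p-values under 0.05). Its shift did not pass the threshold (camera, adjusted p = 0.15; adjusted p = 0.83 with an estimated correlation). Tested by itself with fry, the list had an adjusted p of 0.031, and of 0.28 with TMM scaling. Adjusted over the list alone, 2 of its genes passed, Ski and Tgfbr2, with 0 over all genes tested. Without BDS 21, BDS 25 and BDS 55, the smallest adjusted p of any list was 0.81 (camera). That comparison held only 9 samples and so had less power, and it does not show that the TGF-beta shift rests on those 3 samples. The mean of the TGF-beta list was -0.045, -0.12 and -0.22 in BDS 7, BDS 35 and BDS 43 (log2 difference from the control mean). In control samples it ran from -0.082 to 0.061.

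The JAK-STAT and cytokine receptor list held 31 present genes, 25 with log2 fold changes below 0, 19 below the panel median and 7 at an unadjusted p under 0.05 (camera, adjusted p = 0.15; adjusted p = 0.83 with an estimated correlation). Adjusted over the list alone, 3 genes passed, Il21r, Il6st and Il4ra, and Il4ra also passed in the list of alternative activation and resolution. In the Toll-like receptor and NF-kB list, 22 of 32 genes were below 0 and 18 below the panel median, led by Tlr9, Tlr3 and Tlr5 (adjusted p = 0.56). With no filter on low counts the JAK-STAT, Toll-like receptor and TGF-beta lists passed the threshold (camera, adjusted p = 0.011, 0.037 and 0.043). For all 3 the adjusted p was 0.64 with an estimated correlation. The lists were then compared also with 188 genes near background, whose median log2 difference was 0.15 after scaling. This moved the panel median from -0.10 to -0.03. Of 24 interferon genes, 19 were below 0 and 12 below the panel median, with Ifit2 and Ddx58 among those at an unadjusted p under 0.05 (adjusted p of the list = 0.58). Ifit2 had 70.8 ± 22.9 normalized counts in controls and 48.6 ± 10.7 in BDS. The microglial identity list had 6 of 7 genes below 0 and 5 below the panel median. Its Cx3cr1, the fractalkine receptor, was at 14525 ± 496 and 13436 ± 895, and Runx1 at 3811 ± 132 and 3081 ± 793 (adjusted p of the list = 0.66).

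Phagocytic and Fc receptor genes went both ways. Fcgr1 was at 14015 ± 449 and 12766 ± 576 normalized counts, and Fcgr2b at 4687 ± 839 and 3726 ± 909, while Tyrobp, an adaptor of myeloid receptors, was at 3266 ± 133 and 3747 ± 699. Without BDS 21, BDS 25 and BDS 55 the log2 fold change of Tyrobp turned from 0.20 to -0.055. That list, with 4 of 9 genes below 0 and 2 below the panel median, had an adjusted p of 0.58. Complement genes showed 8 of 12 below 0 and 7 below the panel median (adjusted p = 0.86). The adjusted p was 0.48 for MHC class I presentation, 0.81 for MHC class II presentation, 0.60 for inflammatory cytokines and chemokines, 0.79 for adhesion and migration, and 0.85 for apoptosis and survival. It was 0.68 for both the alternative activation list and the list of immediate-early and activation genes. It was 0.58 for glucocorticoid-responsive genes, of which Fkbp5 was at 1951 ± 144 and 2110 ± 245. Camera takes its direction relative to the rest of the panel. It was up for the cytokine, MHC class II, apoptosis, complement, glucocorticoid, T cell and NK cell lists, whose median log2 fold changes were -0.12, -0.11, -0.07, -0.13, -0.04, -0.06 and -0.05. The medians of the cytokine, MHC class II and complement lists lay below the panel median of -0.10, so the median of a list does not give its direction in camera. MHC class I presentation had a median of 0.05 and a mean of -0.0098.

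**Figure D3:**
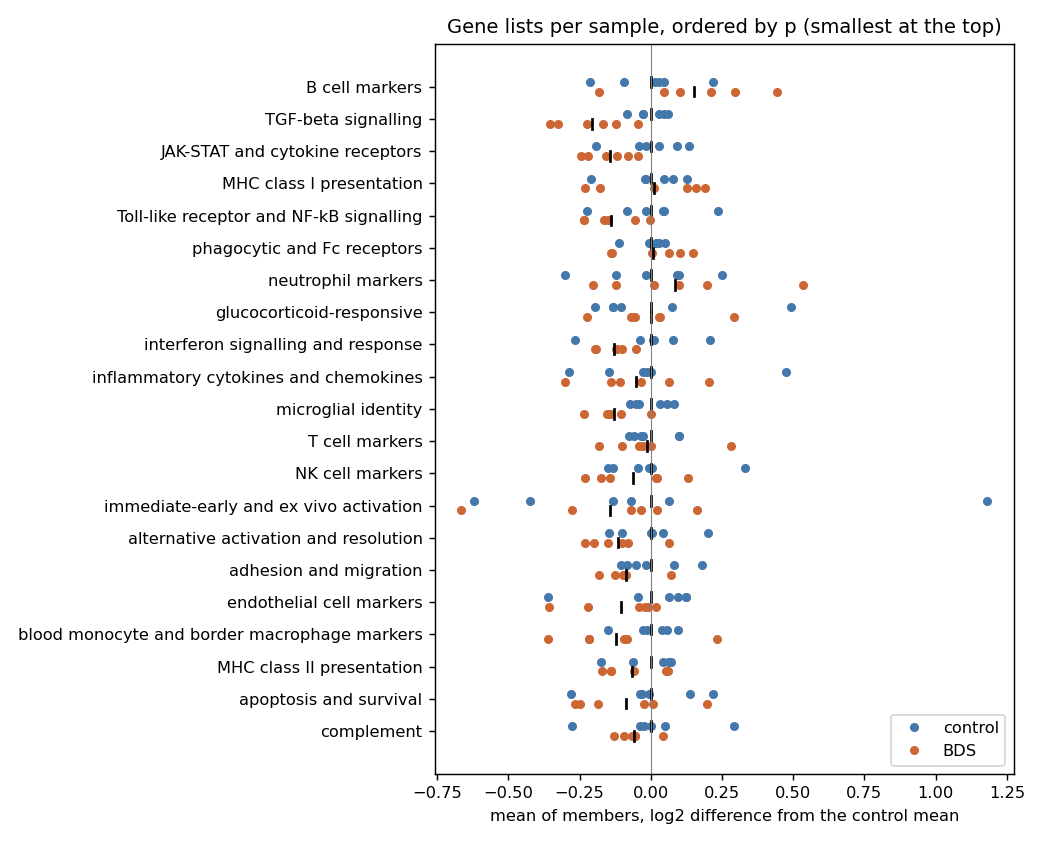
Mean of the present members of each gene list (x axis, log2 difference from the control mean) in each of 6 control and 6 BDS samples, lists ordered by their camera p. Points are samples and black ticks are group means. In no list does the shift relative to the rest of the panel pass the adjusted threshold (camera, smallest adjusted p 0.15). Tested by itself with fry, TGF-beta signalling has an adjusted p of 0.031, and of 0.28 with TMM scaling.

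Markers of other cell types were measured to describe what the sorted samples held. Cd3d, Cd3e and Cd163 were above background in 0 of 12 samples. These 3 were chosen after their values were seen. Of the markers on the panel, 9 of 21 for T cells and 3 of 10 for blood monocytes and border macrophages were present. Of 17 fixed B cell markers, 12 were on the panel and 6 were present, and 4 of these had log2 fold changes above 0, with a list mean of 0.15 (camera, adjusted p = 0.15; adjusted p = 0.83 with an estimated correlation). Blnk was at 3078 ± 155 normalized counts in controls and 3462 ± 372 in BDS, and Tnfrsf13b at 26.5 ± 2.5 and 40.7 ± 15.1. The 2 genes below 0 were Pou2f2, at 843 ± 44 and 752 ± 55, with all 6 BDS samples below the control mean, and Cd79a, at a log2 fold change of -0.16. The sample means of the list were 0.44, 0.29 and 0.21 above the control mean (log2) in BDS 21, BDS 25 and BDS 55, the BDS samples with the lowest housekeeping counts, and 0.10, -0.18 and 0.04 in BDS 7, BDS 35 and BDS 43. With only the genes above background in all samples, the list of 5 genes passed (adjusted p = 0.030; adjusted p = 0.85 with an estimated correlation). The adjusted p was 0.66 for both T cell and NK cell markers, 0.58 for neutrophil markers, and 0.81 for both endothelial and blood monocyte markers. Ccr2, a monocyte receptor, was at 377 ± 76 and 292 ± 73, and Cdh5, an endothelial cadherin, at 145 ± 23 and 116 ± 17. Mast cell markers had 0 present genes, and the astrocyte, neuron and oligodendrocyte markers had 2, Icam5 and Mbp, too few to test.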

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

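The tests of the housekeeping genes, of the shift without 3 samples, of the negative-control probes and of the exchanged pair were chosen after the results had been seen, as were the splits for the counts of 0. The splits for unadjusted p-values and the split of the controls were fixed before their results.

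Several samples stood far from the other 5 of their group; chance alone does this in about 1 of 20 groups, and 13 of 188 did. BDS 7 was high in Fcgr2b (5571 normalized counts), Il1b (201.6), Ccr2 (431.3) and the mean of the adhesion and migration list (0.0698, log2 difference from the control mean). Control 44 was high in H2-K1 (6252), Prf1 (325.4) and the NK cell marker mean (0.33). Control 27 was high in Cd82 (3929) and low in the endothelial marker mean (-0.36), and control 54 was high in Cdh5 (188.4). Control 5 was low in the mean of the phagocytic and Fc receptor list (-0.11). BDS 25 was high in Il6 (38.5) and BDS 21 in Csf1 (338.4).

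Most genes of small p were lower in BDS, on a panel whose median lay at -0.10, at -0.06 without control 44 and at -0.05 with the Rpl19 to Polr2a ratio as covariate. Of 100 splits of the 12 samples, the real one included, 14 gave at least the 44 genes at an unadjusted p under 0.05 of the real one, with 118 in the highest other split, so chance cannot be excluded. For genes past the adjusted threshold the real value was 0 and the highest other 60, and for lists 0 and 4. With a real value of 0 all 100 splits are as large by construction, so these counts say nothing about chance. The 8 housekeeping genes not used for scaling lay 0.087 above the panel median (log2, TMM scaling, bootstrap interval -0.04 to 0.24), which is too wide to tell whether the panel-wide shift may come from the 6 genes used. Without BDS 21, BDS 25 and BDS 55 the median was -0.087, and -0.13 to -0.05 with 1 further sample left out, so those 3 samples as the whole source of the shift cannot be told apart from a shift in all BDS samples.

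For which genes lay lowest, a test that kept samples apart was run. Genes picked as lower in those 3 BDS samples against 3 controls had a median log2 difference from the panel of 0.011 in the other 3 BDS samples against the other 3 controls (range -0.01 to 0.06 over 20 splits of the controls). At the median, genes lower in those 3 samples thus lay near the panel in the other 3 BDS samples. They were picked in those 3 samples, not by their rank in the full comparison. The test therefore does not decide what that ranking rests on. Without those 3 samples the 24 genes of smallest p kept their sign, 10 of them at an unadjusted p under 0.05. Those 24 were picked with all samples, so this does not decide it either. The low housekeeping counts and high Rpl19 to Polr2a ratios of those 3 samples could reflect less or poorer RNA. An effect of separation that was stronger in those animals stays open as untested, since RNA quality was not measured independently.

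The highest other split exchanged control 9 with BDS 7. It called 60 genes past the adjusted threshold, where the real grouping called 0, and gave 118 genes at an unadjusted p under 0.05 against 44. Of the 36 exchanges of 1 control with 1 BDS sample, 2 called any gene, the other being control 5 with BDS 7 (15 genes). Left out of their own group's mean, 5 samples lay nearer the mean of the other group under both scalings: control 9, control 44, BDS 7, BDS 35 and BDS 43. On this scale values below 0 are nearer the other group, and BDS 7 lay farthest (-1.35 with housekeeping scaling, -1.46 with TMM). Control 9 was at -0.93 with housekeeping scaling, and control 44, BDS 35 and BDS 43 at -0.12 to -0.17. With TMM control 9 was at -0.53 and control 44 at -0.69. The position thus sets BDS 7 apart under both scalings, and control 9 only with housekeeping scaling. It neither shows nor excludes a mix-up of the labels of control 9 and BDS 7. That stays open beside spread between litters, and all labels were kept. Without BDS 7, 4 genes passed the adjusted threshold.

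The authors' deposited table lists 10 genes as absent with a p under 0.05, and all 10 are higher in BDS. Among the 188 genes below the limit here, the median log2 difference was 0.15 after scaling and -0.15 in raw counts, and the negative-control probes rose with them after scaling (0.34). Against the negative-control probes of the same sample the median was -0.22 (bootstrap interval over genes -0.28 to -0.18). Raw counts of those probes in BDS were 1.05 times those in controls, while housekeeping counts were 0.80 times. Transcripts at an unchanged level would then also fall against the probes, so this value does not count against a rise. Nor does it decide whether background counts scaled up by low housekeeping counts explain the pattern. The 10 genes themselves lay 0.14 above those probes at the median, 9 of 10 higher, and because they were picked for a small p this decides nothing about them.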

How the results depend on the processing

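The alternatives that dropped 3 samples, added a covariate, subtracted background, used the authors' genes or p-values, or joined fry with TMM or a filter with an estimated correlation were chosen after seeing the data; the others were planned. Cartridge or lane as a block was not run, since the tables give neither, and no paired analysis was possible because the groups share no replicate numbers. The cause of the differences below was not tested.

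Of genes past the adjusted threshold (0 of 357), DESeq2 with housekeeping size factors gave 6 and voom with quality weights 16, leave-one-out gave 0 to 4 (4 without BDS 7), and the other alternatives, the deposited p-values included, gave 0. Of gene lists (0 of 21), no filter gave 3, the genes above background in all samples 1 and fry 1; with an estimated correlation both filters gave 0. Genes lower and higher at an unadjusted p under 0.05 (41 and 3) became 14 and 18 with TMM, 13 and 19 with total counts, 14 and 13 with DESeq2 median ratios, 85 and 11 with voom, 39 and 12 with no filter, 49 and 20 with counts floored at background, 30 and 5 with the authors' 5 housekeeping genes, 42 and 5 with the deposited values and a pseudocount of 10, 59 and 1 with background subtracted, 20 and 0 without the 3 BDS samples lowest in housekeeping counts, 22 and 0 with the housekeeping count and 20 and 0 with the Rpl19 to Polr2a ratio as covariate. Leaving out 1 sample gave 22 to 87 lower and 2 to 10 higher genes: 87 and 8 without BDS 7, 22 and 4 without BDS 55, 23 and 3 without BDS 25, 27 and 3 without control 27, 27 and 7 without control 44, 35 and 6 without control 5, 45 and 9 without BDS 35, and 45 and 10 without BDS 43.

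The 24 genes of smallest p kept their sign in every alternative that tested them. They were picked for small p in these same samples, so this is no independent support. Among the genes named here, signs turned, never past the threshold, as follows (log2). Without the 3 BDS samples: Tyrobp -0.055, Bcl6 0.075, Csf1r -0.095, Ctss -0.11, Cd81 -0.12, C1qb -0.16. With the housekeeping count as covariate: Csf1r -0.0064, Ctss -0.073, Cd81 -0.13, C1qb -0.071. With the Rpl19 to Polr2a ratio as covariate: Il13ra1 0.019, Stat3 0.00048, Bcl6 0.064, Csf1r -0.076, Ctss -0.12, Cd81 -0.20, C1qb -0.16, Tgfbr1 0.067. With 5 housekeeping genes Cd81 was at -0.033, and with background subtracted Cd36 at -0.031. With 1 sample left out, Cd81 ran from -0.037 to 0.070 and H2-K1 from -0.63 to 0.078 (0.078 without control 44). Counts near the negative controls limit genes such as Cybb, Il6 and Tnfrsf13b.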

Other observations

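The test of the activation genes was chosen after their values had been seen. Genes switched on quickly by stimulation or tissue handling varied between samples inside both groups. The list of immediate-early and activation genes held 10 present members, with no Fos, Jun or Egr gene among them. Its mean was 1.18 above the control mean in control 44 and -0.62 in control 9, and in BDS samples it ran from -0.67 in BDS 7 to 0.16 in BDS 43 (log2). Among its members, Tnfaip3, an inhibitor of NF-kB signalling, had 961 ± 211 normalized counts in controls and 736 ± 179 in BDS, and Il1b had 161 ± 39 and 128 ± 36. Cd83 was at 1296 ± 115 and 1150 ± 144.

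Without control 44, the SD of the list mean within groups was 0.29, against a median of 0.10 in 10000 random lists matched on mean count, at percentile 100 of those lists. The list was picked because its members varied together, and lists of co-regulated genes in general would exceed random ones, so this test decides nothing about the source of the variation. The shift of this list between the groups had an adjusted p of 0.68 (camera).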
